A study of Rattus norvegicus with 6 samples.

How the data were processed

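The series holds 6 hybridizations of rat embryo RNA to 2-colour oligonucleotide arrays that carry 43379 gene spots for 41012 probes, beside 1639 control spots. Each array set 1 resorbed embryo against 1 normal embryo of the same group, 1 in the Cy3 (green) and 1 in the Cy5 (red) channel. The 3 groups of 2 arrays were control sires at embryonic day 13 (E13), tamoxifen sires at E13 and tamoxifen sires at E11. Per the labels, sires of the tamoxifen groups had received 0.4 mg/kg/day for 60 days, normal samples were an embryo with its placenta, and resorbed samples were the whole resorbed embryo. Replicate 1 of every group had the normal sample in Cy3, and replicate 2 had it in Cy5, so the replicate number and the dye orientation cannot be told apart. The 4 E13 arrays shared 1 slide and the 2 E11 arrays another, per the file headers. The labels name 12 RNA samples, a different pair for each array, but do not state whether replicates came from different embryos, litters or sires. The integrity numbers are the same in both tamoxifen E11 replicates, at 8.1 in normal and 7.8 in resorbed samples. The same pair also stands for replicate 2 of control E13 and of tamoxifen E13. The p-values measure the spread between these samples, part of which may be technical.

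Spot brightness was read by Agilent Feature Extraction 9.1.3.1, per the file headers. The files give the mean intensity of each spot and its local background in each channel, and the intensity after the scanner software's own background and dye normalization, per the file headers. They also give the log10 ratio of Cy5 over Cy3 after that normalization, per the file headers. The deposited value table holds the same ratios, but the values show that 3 of its columns are log10 and the other 3 are log2: the slopes on the scanner's log10 ratios were 1 or 3.322, with correlations of at least 0.999996. The log2 columns are tamoxifen E13 replicates 1 and 2 and tamoxifen E11 replicate 1. For tamoxifen E13 replicate 1 the labels conflict: the extraction protocols and RNA integrity numbers of its channels are the reverse of its sample names. The expression values went with the sample names, which were used, so the integrity numbers of that array are in doubt. On control E13 replicate 1 they were 8.2 in the normal and 7.1 in the resorbed sample. On each of the remaining arrays they were 8.1 and 7.8.

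Ratios were computed anew from the mean spot intensity and median local background with limma 3.58.1 in R 4.3.3 (statmod 1.5.0). Background was corrected by the normexp method with an offset of 50, dye bias was removed by loess within each array with control spots at weight 0, spots marked by the scanner as non-uniform or as outliers were set to missing, and repeated spots of a probe were averaged. A probe was kept when it was well above background, by the scanner's flag, on both arrays of at least 1 of the 6 kinds of embryo (normal or resorbed in 3 groups), which left 24804 probes. The brightest probe stood for each gene, giving 21104 genes. Other kept probes of a gene could move less, as given below for some genes. Probe names came from the files' accessions and symbols matched to the rat GRCr8 annotation: 10735 probes were named by accession, 5577 by symbol and 3730 by synonym, and 20970 kept the name in the files. Of the genes tested, 11215 had a current symbol and 9889 had only a provisional name or accession. Provisional genes were counted but not named. No coordinates are given, since the probes were not placed on that assembly.

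A linear model with 1 mean per group was fitted to the log2 ratio of resorbed over normal with limma, whose moderated test pools the spread of all 6 arrays. This left 3 residual degrees of freedom and a prior of 3.35. Contrasts were resorbed against normal in each group and over all 3, the tamoxifen minus control difference of that ratio at E13, and the E13 minus E11 difference in the tamoxifen groups. Normal with normal and resorbed with resorbed embryos were compared across groups by separate-channel analysis (Aquantile normalization, an intraspot correlation of 0.034, 6 residual degrees of freedom and a prior of 3.47), on 21096 genes. A gene passed at a Benjamini-Hochberg adjusted p below 0.05, and all adjusted p of single genes are of this kind. Where 1 side of a ratio was never well above background, or was saturated on every array, the fold is given as "at least". The dim side was then set at its own level or at the lowest level of any probe well above background in that channel, whichever was higher, and the saturated side at its measured level.

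For 27 gene lists, limma's camera tested whether list members had moved further than other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. The form with an estimated correlation takes its p-value from the 3 residual degrees of freedom, and the preset form does not. It is therefore much stricter, whatever the correlation within a list. The fry test asked whether members moved, on balance, 1 way, without setting them against other genes. The lists were apoptosis, cell cycle, complement and coagulation, decidua, DNA methylation and chromatin, endothelium and angiogenesis, erythroid cells, extracellular matrix and cartilage, heart and skeletal muscle, heat shock and stress response, housekeeping genes, Hox and axial patterning, hypoxia and glycolysis, IGF signalling, maternally and paternally expressed imprinted genes, inflammatory cytokines and chemokines, macrophages and leukocytes, natural killer and T cells, nervous system, neutrophils, proteases and their inhibitors, ribosomal proteins, steroid hormone and oestrogen response, trophoblast and placental hormones, yolk sac and visceral endoderm, and Y-linked genes. The last had fewer than 5 measured members and was not tested, which left 26. Of their 642 symbols, 591 were on the array. Several lists share genes: 4 measured members each of the decidua, IGF and maternally imprinted lists, and 3 each of the housekeeping and protease lists, are also in another list.

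Groups, comparisons, the 27 gene lists and all alternatives but 1 were fixed before the data were examined. The closing section names that alternative, and the lists and tests, that were chosen later. Fixed too was the rule for naming genes. Per comparison it takes the 10 largest rises and the 10 largest falls that passed and had the same sign on every array concerned. Where fewer than 10 passed, the smallest unadjusted p with at least 2-fold change fill each direction up to 5, stated as not passing. It adds up to 4 members of each list with the largest change, and Igf2, H19, Afp, Hbb, Prl3b1, Prl8a2, Cd68, S100a9, Vegfa and Mki67 where measured. H19 was not measured. A gene named outside this rule is said to have been chosen after its values were seen.

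The number of arrays limits the precision: the median standard error of a gene's log2 ratio was 0.154 in a group, 0.0887 over all 3 groups, 0.217 for a difference of groups and 0.166 between channels. The scripts were tested on simulated data with 200 changed genes. For resorbed against normal in control E13, 8.96% of the 1.5-fold, 73.1% of the 2-fold and 100% of the 4-fold changes among 21104 genes were recovered. For the tamoxifen minus control difference, the shares were 0%, 5.97% and 98.5%, and for the E13 minus E11 difference 0%, 8.96% and 93.9%. For tamoxifen against control in resorbed embryos, over 21096 genes, they were 14.9%, 68.7% and 98.5%. Noise was drawn independently for each gene. With only 200 changed genes the adjusted threshold is stricter than in the real control E13 comparison, where 9468 genes passed. The simulated shares therefore do not give the power of resorbed against normal embryos.

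The alternatives were the scanner's own ratios, the deposited value table, no background correction, median centring in place of loess, scaling between arrays, no filter and a strict filter, a dye coefficient (which is also the replicate number as a block), moderation with a trend and robust option, fits on the compared arrays alone, other channel normalizations, exchanged channels of tamoxifen E13 replicate 1, and leaving out each array. Leaving out an array left its group with 1 array in 1 dye orientation. In that group a dye effect then no longer cancels, and the spread comes from the other groups. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.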

Results

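Gene expression was measured in resorbed and normal rat embryos with 6 two-channel whole-genome arrays, in 3 groups of 2. The embryos were sired by control males or by males given tamoxifen, a selective oestrogen receptor modulator, and were taken at embryonic day 13 (E13, both kinds of sire) or at E11 (tamoxifen only). The animals were Holtzman rats, an outbred strain. Resorption is the breakdown of a dead embryo within the uterus. Each array compared RNA of a resorbed with RNA of a normal embryo of its group, and the normal samples included the placenta. Between 51.79% and 61.42% of the 41012 probes were well above background in the normal samples, and between 49.03% and 55.58% in the resorbed samples. After filtering, 21104 genes were tested. The ratios of 5 arrays correlated with each other across genes at r of 0.8228 to 0.9394, whereas tamoxifen E13 replicate 2 stood apart, at 0.6605 to 0.8106. The spread of its log2 ratios (SD) was 0.7249, against 0.9195 on the other array of its group and 0.9366 and 0.9382 on the control E13 arrays. Genes are not independent replicates, so these correlations describe the arrays only.

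The first question was which genes differ between a resorbed and a normal embryo when the sire was a control. In control E13, most measured genes of the yolk sac, nervous system, erythroid and cell cycle lists were lower in resorbed embryos, while 11 of 17 genes of the decidua, the maternal tissue around the embryo, and 13 of 22 macrophage and leukocyte genes were higher. The secreted phosphoprotein Spp2 fell by 5.24 ± 0.23 (SE, n = 2 arrays, adjusted p = 9.01e-05) in log2 units, and the plasma proteins albumin (Alb) and transferrin (Tf) fell by 4.79 ± 0.27 and 4.69 ± 0.14. As means over the arrays of all groups, 3 Alb probes ranged from -3.62 to -0.79. Alpha-fetoprotein (Afp), the main plasma protein of the fetus, was at least 21.7-fold lower (log2 -4.44 ± 0.37, adjusted p = 0.000458), with its normal samples at saturation. Sv2b, a synaptic vesicle glycoprotein, rose most, by 3.87 ± 0.28 (adjusted p = 0.000308), and Ccdc37 rose by 3.71 ± 0.16. In all, 9468 of 21104 genes passed, 4416 higher and 5052 lower, and 4205 of these changed at least 2-fold. Of the genes that passed, 1471 were near background on 1 side, so that their folds are lower bounds.

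Embryonic tissue lists fell together in control E13. Of 27 measured yolk sac genes, 24 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 change was -2.56. Of 26 nervous system genes 24 fell (median -1.95), among them the migrating-neuron protein Dcx at -4.37 ± 0.21 and the RNA-binding protein Elavl4, which was at least 20.3-fold lower. As means over the arrays of all groups, 4 Elavl4 probes ranged from -4.14 to -0.65. Of 21 erythroid genes 17 fell (median -2.02), the embryonic globin Hbg1 by at least 19.2-fold. Counts for both lists were the same adjusted over the list alone. Of 32 cell cycle genes 29 fell and 3 rose (median -2.32, the same counts adjusted over the list alone), with the spindle checkpoint kinase Bub1b at -3.92 ± 0.24 and the proliferation marker Mki67 at -3.22 ± 0.21. The bone and cartilage collagens Col1a1 and Col2a1 fell by 4.19 ± 0.19 and 3.37 ± 0.13, and the muscle myosins Myh3 and Myh7 by 3.54 ± 0.14 and 3.40 ± 0.14. Over all groups, 3 Col1a1 probes ranged from -3.84 to -0.99. With camera at its preset correlation, the adjusted p was 3.93e-12 for yolk sac, 3.93e-12 for nervous system, 3.02e-08 for erythroid cells and 1.19e-10 for cell cycle. None held with an estimated correlation, where adjusted p = 0.0932, 0.302, 0.0932 and 0.332 in the same order.

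Many genes of the maternal and immune cell lists rose in control E13. Of 17 decidua genes 11 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 1.42. The uterine transcription factors Hoxa11 and Hand2 rose by 2.48 ± 0.23 and 2.23 ± 0.22, and the progesterone receptor Pgr by 2.10 ± 0.23. Over all groups, 2 Pgr probes read 0.33 and 1.64. Of 22 macrophage and leukocyte genes 13 rose and 0 fell, also adjusted over the list alone (median 0.89). The lysozyme Lyz2 rose by 2.02 ± 0.29, and the endotoxin co-receptor Cd14 by 2.42 ± 0.40. The macrophage marker Cd68 rose by 1.95 ± 0.31 and the neutrophil protein S100a9 by 1.55 ± 0.27. Among proteases, stromelysin-2 (Mmp10) and cathepsin K (Ctsk) rose by 3.01 ± 0.43 and 2.56 ± 0.31. Of 23 genes of hypoxia and glycolysis 10 rose and 2 fell (11 and 4 adjusted over the list alone, median 0.33), with the mitochondrial death protein Bnip3 at 2.61 ± 0.33. Vegfa, the main vascular growth factor, did not pass (0.70 ± 0.24, adjusted p = 0.0536), except in fits without tamoxifen E13 replicate 1 or 2 (0.00678). Camera gave adjusted p = 0.000505 for decidua, 0.000505 for macrophages and 0.0073 for hypoxia. With an estimated correlation adjusted p = 0.332, 0.411 and 0.377.

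Placental genes differed in direction and between the arrays of control E13. Of 28 trophoblast genes 13 fell and 2 rose, also adjusted over the list alone (median -1.57; camera adjusted p = 0.0073, but adjusted p = 0.411 with an estimated correlation). The list median was -0.29 on replicate 1 and -2.52 on replicate 2, and without replicate 2 the camera adjusted p was 0.561. The placental cathepsin Ctsm fell by 3.54 ± 0.24. The prolactin-family hormone Prl2a1 read -3.69 ± 0.84 (adjusted p = 0.0141), with -1.82 on replicate 1 and -5.56 on replicate 2, and placental lactogen II (Prl3b1) did not pass at -2.04 ± 0.95 (adjusted p = 0.125), but did at -4.31 without replicate 1 (0.0103). The decidual prolactin Prl8a2 rose instead, at least 3.34-fold higher (1.74 ± 0.34, adjusted p = 0.00804). Insulin-like growth factor 2 (Igf2), an imprinted gene, fell by 2.97 ± 0.52 (adjusted p = 0.00514), and the placental growth restrainer Phlda2, also imprinted, by 3.58 ± 0.14. Leaving out replicate 1 left 4528 genes past the threshold and leaving out replicate 2 left 5077. Of 108 named genes that passed in control E13, 19 and 26 lost their call in these fits. Without replicate 1 the mast cell protease Mcpt8 (2.66, adjusted p = 0.0585), the placental prolactin Prl7b1 (-4.02, 0.0973) and Adm (2.28, 0.0518) were among them. Without replicate 2 the calls of Prl2a1 (-1.82, adjusted p = 0.101), Prl8a2 (1.19, 0.0981), Igf2 (-2.17, 0.0689), Cd14 (2.00, 0.0629), Cd68 (1.80, 0.053) and S100a9 (1.20, 0.0741) were among those that ended.

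The same question was put for embryos of tamoxifen sires at E13. Most measured genes of the yolk sac, nervous system and cell cycle lists again fell, and 12 of 17 decidua and 14 of 23 hypoxia genes rose, as did 8 of 22 macrophage and leukocyte genes and 9 of 24 proteases. Spp2 fell by 5.18 ± 0.23 (adjusted p = 9.37e-05), and Col1a1 and Tf changed by -4.66 ± 0.19 and -4.48 ± 0.14 (n = 2 arrays). The globins Hbe2 and Hbg1 were at least 24.9-fold and 24.6-fold lower, and Afp at least 16.6-fold lower. Cxcl2 rose by 3.31 ± 0.59 (adjusted p = 0.00773), Sv2b by 2.86 ± 0.28, and the polyamine-degrading enzyme Sat1 by 2.85 ± 0.24. Past the threshold were 7247 genes, 3034 higher and 4213 lower, of which 3114 changed at least 2-fold.

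In tamoxifen E13, 22 of 27 yolk sac genes, 24 of 26 nervous system genes and 26 of 32 cell cycle genes fell, also adjusted over each list alone, with medians of -2.65, -1.86 and -2.00. Camera gave adjusted p = 1.05e-12, 1.48e-13 and 5.69e-10 for these 3 lists, and with an estimated correlation adjusted p = 0.0688, 0.247 and 0.298. Of 24 proteases and inhibitors 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.83; camera adjusted p = 0.000679, and adjusted p = 0.272 with an estimated correlation). Mki67 fell by 2.96 ± 0.21 and the topoisomerase Top2a by 3.27 ± 0.18. Of 17 decidua genes 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 1.21). Their camera adjusted p was 4.46e-05, and with an estimated correlation adjusted p = 0.247. Of 23 hypoxia and glycolysis genes 14 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.72), with Bnip3 at 2.33 ± 0.33, the vasodilator peptide Adm at 2.25 ± 0.38 and Vegfa at 0.81 ± 0.24 (adjusted p = 0.0407). Camera gave adjusted p = 2.72e-05 for hypoxia and 0.00245 for the heat shock and stress list, 10 of whose 20 genes rose and 2 fell (12 and 4 adjusted over the list alone). With an estimated correlation adjusted p = 0.247 for each. Hspa1a rose by 2.51 ± 0.42 and the stress transcription factor Ddit3 by 2.22 ± 0.27.

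Some immune and placental gene calls of tamoxifen E13 depended on single arrays. Of 22 macrophage genes 8 rose and 2 fell (8 and 3 adjusted over the list alone; median 0.55; camera adjusted p = 0.0104, and adjusted p = 0.551 with an estimated correlation). The median of that list was 0.89 on replicate 1 and 0.20 on replicate 2, and that of the natural killer and T cell list 1.16 and -0.37. Of the latter 1 of 10 genes rose, and 0 did adjusted over the list alone. Cd68 rose by 1.80 ± 0.31 and S100a9 by 1.90 ± 0.27. Of 28 trophoblast genes 9 fell and 1 rose, also adjusted over the list alone (median -0.78; camera adjusted p = 0.0468, and adjusted p = 0.551 with an estimated correlation). The placental cathepsin Ctsj fell by 3.90 ± 0.46, Igf2 by 1.91 ± 0.52 (adjusted p = 0.0316), and Prl8a2 rose by 1.59 ± 0.34, while Prl3b1 did not pass (-2.48 ± 0.95, adjusted p = 0.0892). Without replicate 1 the count was 3927, 19 of 108 named genes that had passed lost their call (4 without replicate 2), the list calls of macrophages (0.318) and trophoblast (0.12) ended, and so did those of Cxcl2 (2.42, 0.0614), Igf2 (-0.93, 0.248), Prl8a2 (1.26, 0.112) and Vegfa (0.31, 0.307), while Cd68 and Adm were 1.16 and 1.49. Without either control E13 array Vegfa had adjusted p = 0.071 and Prl3b1 0.00773, and without either tamoxifen E11 array Vegfa had 0.0714 and Igf2 0.0563. With replicate 1 read in the channel order of its extraction protocols, limma called 0 genes (419 at an unadjusted p below 0.05), and with the 2 arrays of this group fitted alone it called 3027.

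At E11, the largest falls among genes with a current name were those of prolactin-family placental hormones. The prolactin-family genes Prl7a3, Prl2a1 and Prl4a1 changed by -5.63 ± 1.09 (adjusted p = 0.0123), -5.01 ± 0.84 (adjusted p = 0.00814) and -4.94 ± 1.08 (adjusted p = 0.0179), the placental homeobox gene Rhox9 fell by 4.47 ± 0.75, and Prl3b1 was at least 15.1-fold lower (n = 2 arrays). Spp2 fell by 4.82 ± 0.23, Afp was at least 19.6-fold lower, and Igf2 fell by 3.60 ± 0.52. The iron hormone hepcidin (Hamp) rose most, by 2.76 ± 0.28, followed among named genes of known role by the interleukin-33 receptor Il1rl1 at 2.26 ± 0.30 and the mast cell protease Mcpt1 at 2.22 ± 0.25. Of 6779 genes past the threshold, 2884 were higher and 3895 lower, and 2798 changed at least 2-fold. Far fewer genes were called higher at E11 with median centring in place of loess, as given below, so calls of rises depend on that choice. Without replicate 1 or replicate 2 none of these placental genes passed: Prl7a3 had adjusted p = 0.131 (-5.11) and 0.0867 (-6.15), Prl2a1 0.1 and 0.0736, Prl4a1 0.158 and 0.115, Rhox9 0.0924 and 0.0801, and Prl3b1 0.163 and 0.159. Igf2 did not pass either (0.071 and 0.0615), nor did Il1rl1 without replicate 1 (1.73, 0.0598), whereas Spp2, Afp, Hamp and Mcpt1 passed without either array.

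At E11, 15 of 28 trophoblast genes fell and 2 rose (17 and 2 adjusted over the list alone, median -1.72), with camera adjusted p = 0.00173 and adjusted p = 0.436 with an estimated correlation. Of 27 yolk sac genes 22 fell, of 32 cell cycle genes 29, and of 26 nervous system genes 21 (22, 29 and 23 adjusted over each list alone), with medians of -2.47, -2.14 and -1.63. Their camera adjusted p were 5.33e-12, 6.78e-12 and 2.7e-11, and with an estimated correlation adjusted p = 0.079, 0.36 and 0.267. Of 17 decidua genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 1.06; camera adjusted p = 0.000134, and adjusted p = 0.36 with an estimated correlation). Hypoxia and stress lists did not pass camera at E11: of 23 hypoxia genes 2 rose and 2 fell (1 and 0 adjusted over the list alone; median 0.02; adjusted p = 0.387), and the stress list had a median of 0.02 (adjusted p = 0.599). Bnip3 (1.04 ± 0.33, adjusted p = 0.0529), Adm (1.13 ± 0.38, 0.0661) and Vegfa (-0.05 ± 0.24, 0.899) did not pass, though Bnip3 (0.00169) and Adm (0.014) did without tamoxifen E13 replicate 1 or 2. The mitochondrial chaperones Hspe1 and Hspd1 fell by 1.69 ± 0.22 and 1.43 ± 0.28, and the leukocyte surface protein Cd52 rose by 1.95 ± 0.16. Leaving out replicate 1 left 852 genes, and leaving out replicate 2 left 1086. Of 108 named genes that passed, 58 and 52 lost their call in these fits, among them Hspd1 (0.107 and 0.125) and, without replicate 2, Hspe1 (-1.47, 0.0625).

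Over all 3 groups, some plasma protein, globin and other genes of the embryo again fell. Spp2 fell by 5.08 ± 0.13 (SE, n = 6 arrays, adjusted p = 3.78e-06), and Tf, the growth regulator Gpc3 and the apolipoprotein Apoa1 changed by -4.38 ± 0.08, -4.16 ± 0.07 and -4.12 ± 0.09. Hbg1 was at least 21.6-fold and Afp at least 19.2-fold lower. Sv2b rose by 2.89 ± 0.16, Sat1 by 2.50 ± 0.14, the neuropeptide galanin (Gal) by 2.47 ± 0.14, and the dopamine transporter Slc6a3 by 2.46 ± 0.13. Of 21104 genes 13155 passed, 6093 higher and 7062 lower, and 3378 changed at least 2-fold. With arrays centred on their medians in place of loess, the median of all genes moved by -0.241 in control E13, -0.087 in tamoxifen E13, -0.106 in tamoxifen E11 and -0.151 over all 3. The number past the threshold was then 3700, 1645, 1298 and 7701, and the share of these that were higher was 11.9%, 8.15%, 1.62% and 25.9%, against 46.6%, 41.9%, 42.5% and 46.3% with loess. Rises are therefore relative to the middle of the genes at each brightness.

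Most measured genes in the lists of embryonic tissue, growth and gene regulation were lower over all 3 groups. As lists, none held with an estimated correlation, as given below. Of 27 yolk sac genes 23 fell (median -2.52), of 32 cell cycle genes 29 (-2.12), of 26 nervous system genes 24 (-1.77), of 23 heart and muscle genes 18 (-0.97), and of 16 genes of DNA methylation and chromatin 14 (-1.14), the corepressor Trim28 by 1.71 ± 0.08. Counts were the same adjusted over each list alone. Some members rose: the mitotic kinase Aurkb (1.03 ± 0.10) and the nucleotide reductases Rrm1 and Rrm2 (0.98 ± 0.13 and 0.90 ± 0.09), all of the cell cycle list and chosen after their values were seen, and a second, dimmer Aurkb probe read -1.74. Of 21 erythroid genes 18 fell and 1 rose (18 and 2 adjusted over the list alone, median -1.97), of 19 Hox and axial patterning genes 13 fell and 2 rose (14 and 2, median -0.61), of 25 matrix and cartilage genes 16 fell and 6 rose (median -1.08), and of 13 IGF genes 9 fell and 2 rose (median -1.28). The receptor adaptor Grb10 fell by 3.03 ± 0.10 and Igf1 by 1.86 ± 0.11. These brightest probes also fell most: 3 Grb10 probes ranged from -3.03 to -1.25, and 4 Igf1 probes from -1.86 to 0.11. Of 28 trophoblast genes 16 fell and 2 rose (median -1.50), and of 13 paternally expressed imprinted genes 10 fell and 1 rose (median -0.94), where Dlk1, related to the Notch ligands and chosen after its values were seen, rose by 1.33 ± 0.11 and the membrane proteolipid Nnat fell by 3.12 ± 0.09. Counts for these 4 lists were again the same adjusted over each list alone.

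Camera called these 11 lists lower over all 3 groups. For yolk sac, cell cycle, nervous system, heart, and methylation the adjusted p were 5.07e-10, 3.02e-09, 4.31e-10, 3.69e-06 and 3.04e-05. With an estimated correlation the same lists had adjusted p = 0.104, 0.356, 0.32, 0.104 and 0.32. For erythroid cells, Hox, matrix, IGF, trophoblast and paternally expressed genes the adjusted p were 2.49e-07, 0.00218, 0.0165, 0.0165, 0.00539 and 0.00812, and with an estimated correlation adjusted p = 0.104, 0.399, 0.399, 0.32, 0.399 and 0.32. No list in any comparison held its camera call with an estimated correlation. That form rests on 3 residual degrees of freedom, so failing it does not show that a list stayed still. The fry test, which does not set a list against other genes, gave adjusted p below 0.05 for 22 of the 26 lists over all 3 groups.

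Lists of the mother's tissue and of immune cells were higher over all 3 groups. Of 17 decidua genes 13 rose and 2 fell (median 1.24), with Hand2 at 1.80 ± 0.13, Hoxa11 at 1.79 ± 0.13 and the phosphatase Alpl at -1.65 ± 0.21. Of 22 macrophage genes 13 rose and 1 fell (median 0.69), of 9 neutrophil genes 6 rose (0.52), and of 10 natural killer and T cell genes 6 rose (0.82), the last with a median of -0.37 on tamoxifen E13 replicate 2. Cd68 rose by 1.64 ± 0.18, Lyz2 by 1.61 ± 0.17, the decoy interleukin-1 receptor Il1r2 by 1.87 ± 0.13 and S100a9 by 1.57 ± 0.16. Of 20 cytokine genes 14 rose and 1 fell (median 0.72), where Cxcl2 rose by 2.36 ± 0.34 and the adhesion molecule Vcam1 fell by 2.54 ± 0.10. Of 24 protease genes 15 rose and 2 fell (median 0.83), with Mmp10 at 2.41 ± 0.25 and Ctsk at 2.17 ± 0.18. Of 23 hypoxia genes 12 rose and 3 fell (median 0.25), and of 20 stress genes 12 rose and 5 fell (median 0.57). Ddit3 rose by 2.03 ± 0.16, whereas the chaperone Hspe1 fell by 1.43 ± 0.13. All counts of this paragraph were the same adjusted over each list alone. Camera gave adjusted p = 0.000264 for decidua, 0.00173 for macrophages, 0.00812 for neutrophils, 0.0267 for natural killer and T cells, 0.00185 for cytokines, 0.00218 for proteases, 0.00539 for hypoxia and 0.0284 for stress. With an estimated correlation adjusted p = 0.339, 0.428, 0.339, 0.502, 0.423, 0.339, 0.369 and 0.356 in the same order. Without tamoxifen E13 replicate 2 the stress list no longer passed camera (adjusted p = 0.0715).

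The remaining 7 lists moved both ways or little over all 3 groups, and camera called none of them. Of 29 apoptosis genes 12 rose and 10 fell (median 0.09, camera adjusted p = 0.354), with the inflammatory caspase Casp4 at 1.90 ± 0.13 and the death ligand Faslg at -1.91 ± 0.11. Of 20 complement and coagulation genes 10 rose and 6 fell (12 and 6 adjusted over the list alone). Their median was 0.57 and camera's direction upward (adjusted p = 0.265), but fry's direction was downward (adjusted p = 0.0617), with prothrombin (F2) at -3.40 ± 0.08 and complement C2 at 1.85 ± 0.19. Of 18 endothelial genes 8 rose and 4 fell (median 0.26, camera adjusted p = 0.249), the vessel-destabilising factor Angpt2 by 1.98 ± 0.24 and the tight junction protein Cldn5 by -1.44 ± 0.08. Of 14 steroid and oestrogen response genes 5 rose and 2 fell (median 0.10, camera adjusted p = 0.197), with the glucocorticoid-activating enzyme Hsd11b1 at 2.27 ± 0.11 and Pgr at 1.64 ± 0.13. In tamoxifen E11 the median of that list was 0.17 and its mean -0.09, and in control E13 the endothelial median was 0.20 while fry's direction was downward. Of 14 maternally expressed imprinted genes 8 fell and 4 rose (median -0.85, camera adjusted p = 0.0833), Phlda2 by -3.31 ± 0.08, and the cell cycle inhibitor Cdkn1c was at least 9.39-fold lower. Of 32 ribosomal protein genes 9 fell and 1 rose (median -0.14, camera adjusted p = 0.124), and of 14 housekeeping genes 7 fell and 3 rose (median -0.26, camera adjusted p = 0.255). Apart from complement, counts were the same adjusted over each list alone.

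**Figure D1:**
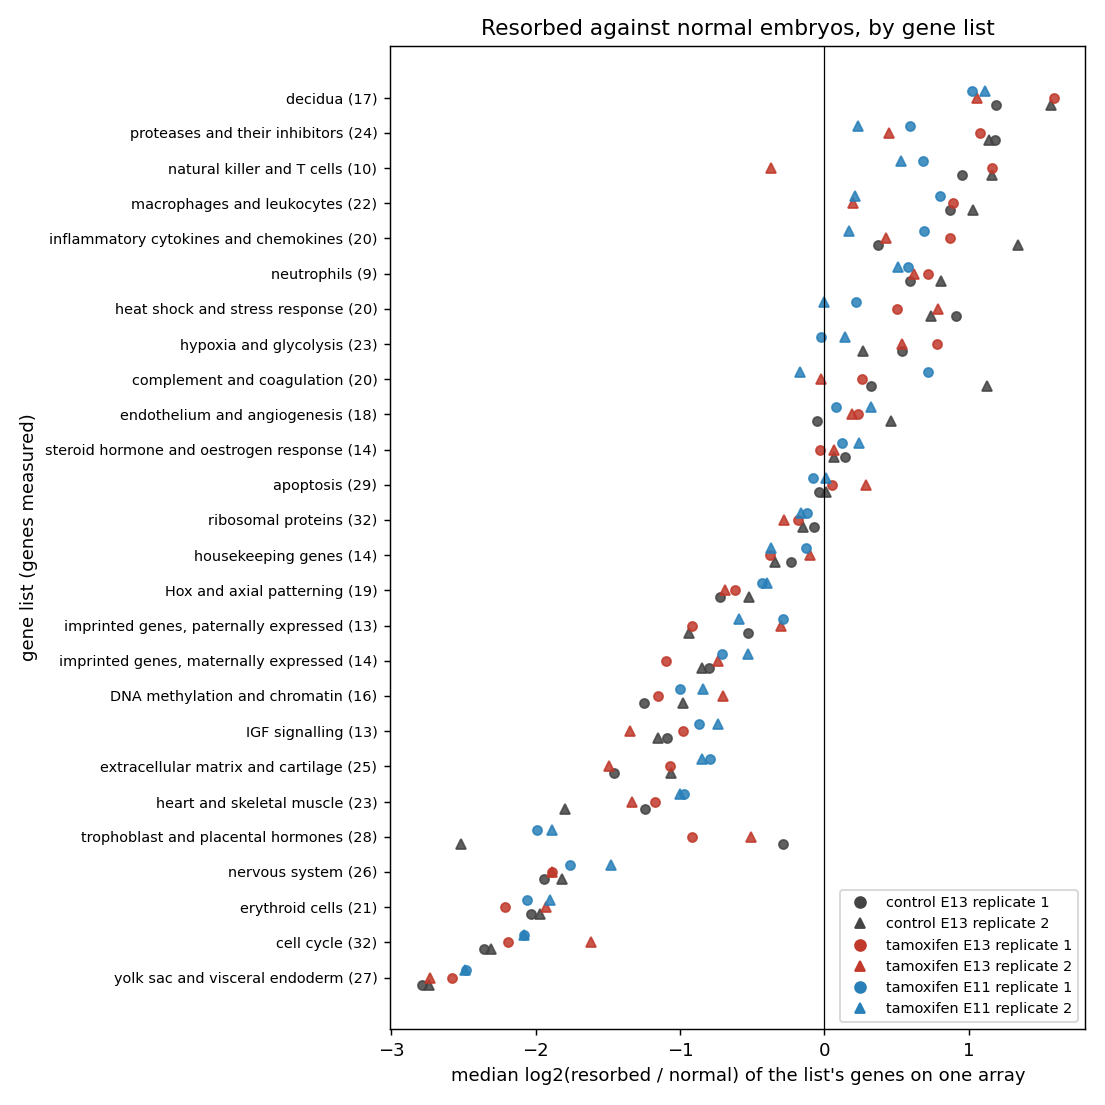
Median log2 ratio of resorbed over normal embryos (horizontal axis, log2 units) of the measured genes of each of 26 lists, with 1 point per array, colours for the 3 groups and circles or triangles for replicate 1 or 2. Yolk sac medians lay between -2.79 and -2.48 on the 6 arrays and decidua medians between 1.02 and 1.59, whereas the trophoblast median ranged from -2.52 to -0.29.

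The 3 groups were compared with each other to ask how far the changes in resorbed embryos were shared. Across all 21104 genes the ratios of tamoxifen E13 followed those of control E13 with Pearson's r of 0.95 and Spearman's rho of 0.9291, and a slope of 0.809. The groups share no array, but genes are not independent replicates and all groups share 1 estimate of the spread. Of the genes past the threshold in both, 2813 were higher and 3836 lower in each, where independent lists of these sizes would share 635 and 1009. The glucose transporter Slc2a1, chosen after its values were seen, was the 1 gene called in opposite directions, at -0.49 ± 0.12 in control E13 (adjusted p = 0.0153) and 0.38 ± 0.12 in tamoxifen E13 (adjusted p = 0.0452). Tamoxifen E11 followed control E13 with r of 0.9088 and rho of 0.908 (slope 0.734). They shared 2536 higher and 3430 lower genes, against 603 and 932 for independent lists, and 10 genes had opposite calls. Between the tamoxifen groups r was 0.8574 and rho 0.8443 (slope 0.813), with 2057 higher and 2911 lower genes shared, against 415 and 778, and 14 opposite calls. In all 3 groups 4897 genes passed, of which 2034 were higher and 2856 lower in each and 7 had mixed signs.

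**Figure D2:**
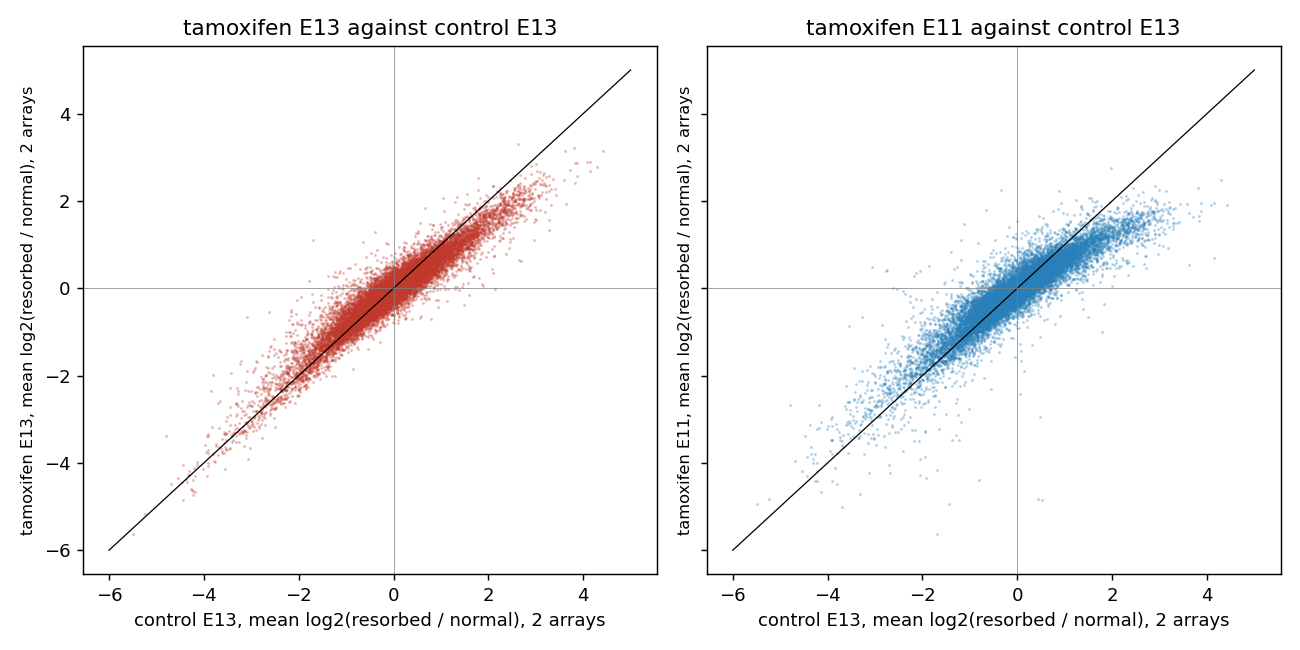
Log2 ratio of resorbed over normal embryos in the tamoxifen E13 group (one panel) and the tamoxifen E11 group (other panel) against that in control E13, both axes in log2 units, 1 point per gene for 21104 genes, with the line of equal change. Points follow the line in both panels (r of 0.95 and 0.9088), with slopes of 0.809 and 0.734, below 1.

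**Figure D3:**
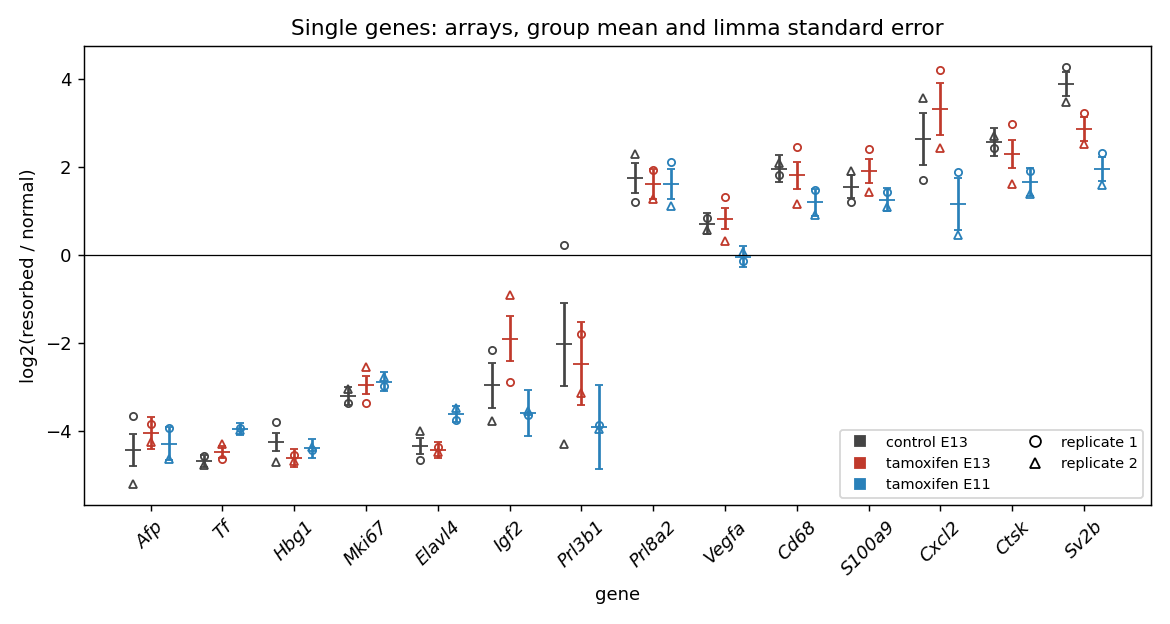
Log2 ratio of resorbed over normal embryos (vertical axis, log2 units) for 14 genes in the 3 groups: points are arrays, and bars the group mean with its standard error from limma. Afp, Tf, Hbg1, Mki67 and Elavl4 lay below -2 on every array shown, whereas Prl3b1 ranged from -4.31 to 0.23.

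Whether paternal tamoxifen altered the difference between resorbed and normal embryos was tested as the difference of the ratios at E13. For no single gene did this difference pass. The log2 ratio of Alb was 1.40 ± 0.38 higher in tamoxifen E13 than in control E13 (n = 2 arrays in each), the muscle ubiquitin ligase subunit Asb2 differed by -1.36 ± 0.39 and Il1rl1 by -1.40 ± 0.43, but the adjusted p of each was 1. Limma called 0 of 21104 genes, and 556 had an unadjusted p below 0.05, fewer than the 1055 that 5% would give. These counts do not show that the ratios were alike. With 2 arrays in each group, 5.97% of simulated 2-fold changes were recovered for this difference. Igf2 (1.06 ± 0.73), Afp (0.39 ± 0.52), Mki67 (0.25 ± 0.30) and Prl8a2 (-0.15 ± 0.48) did not pass either. The 4 arrays of this comparison shared a slide, and a fit on them alone also called 0 genes. Without tamoxifen E13 replicate 1, Asb2 differed by -1.98, but the tamoxifen group then rested on 1 array in 1 dye orientation.

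Camera at its preset correlation called 6 lists for the difference of the tamoxifen and control ratios at E13, while 0 of their members passed singly. None of the 6 held with an estimated correlation (adjusted p = 0.82 each), and the fry test called 0 of 26 lists. The median difference was 0.35 for cell cycle (camera adjusted p = 5.31e-07), 0.50 for trophoblast (0.00344), 0.09 for yolk sac (0.00803) and 0.10 for hypoxia genes (0.0242). It was -0.65 for natural killer and T cell genes (0.0005) and -0.34 for macrophage genes (0.000673), again with adjusted p = 0.82 at an estimated correlation. Adjusted over the list alone, 1 hypoxia gene was higher and no member of the other 5 lists passed. The median and mean had opposite signs for paternally expressed imprinted genes (-0.02 and 0.14) and the steroid list (-0.12 and 0.05), and camera and fry had opposite directions for Hox, nervous system and paternally expressed imprinted genes, none of which passed. Without tamoxifen E13 replicate 2, the calls of cell cycle (adjusted p = 0.681), macrophage (0.953), natural killer and T cell (0.782) and trophoblast genes (0.215) ended. Without control E13 replicate 2, those of hypoxia (0.743) and yolk sac genes (0.395) ended and trophoblast genes passed in the other direction (0.038), and without tamoxifen E13 replicate 1 the hypoxia (0.962) and yolk sac (0.0818) calls ended too.

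The E13 and E11 tamoxifen groups were compared to ask whether the loss differed with stage. The opioid precursor proenkephalin (Penk) was lower in resorbed relative to normal embryos at E13 than at E11 by 3.27 ± 0.23 (adjusted p = 0.047), the actin regulator Rflnb by 2.87 ± 0.23 (adjusted p = 0.047), the lens crystallin Cryba1 by 2.43 ± 0.20 (adjusted p = 0.047), the kininogen Kng2 by 2.12 ± 0.18 (adjusted p = 0.0493) and the membrane skeleton protein Add2 by 1.98 ± 0.16 (adjusted p = 0.047). With 2 genes of provisional name, these were the 7 genes past the threshold, and 1870 had an unadjusted p below 0.05. Over the arrays of all groups, 2 Cryba1 probes had mean log2 ratios of -1.68 and -0.31, and only the brighter was tested. Hspa1a (3.52 ± 0.59, adjusted p = 0.262) and the placental lactogen Prl3d4 (6.02 ± 1.13, adjusted p = 0.285) had wide differences that did not pass. Day and slide cannot be told apart here. The 7 calls were sensitive to the fit: 0 genes passed without control E13 replicate 1 or 2, without tamoxifen E11 replicate 1 or 2, or without tamoxifen E13 replicate 2 (Penk: adjusted p = 0.191, 0.191, 0.392, 0.191 and 0.0938), and 100 passed without tamoxifen E13 replicate 1.

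For the E13 minus E11 difference camera at its preset correlation called 8 lists, while over all genes 0 of their members passed singly and fry called 0 of 26 lists. The median difference was 0.52 for hypoxia (camera adjusted p = 6.06e-10), 0.60 for stress (2.62e-07) and 0.41 for protease genes (0.046). These had adjusted p = 0.356, 0.356 and 0.73 with an estimated correlation. The median difference was -0.55 for nervous system (6.06e-10), -0.32 for heart and muscle (3.61e-05), -0.42 for matrix (0.000628), -0.14 for Hox (0.018) and -0.15 for yolk sac genes (0.0318). For these lists adjusted p = 0.361, 0.356, 0.644, 0.756 and 0.361 with an estimated correlation. The median and mean had opposite signs for DNA methylation (-0.08 and 0.03) and for maternally (-0.17 and 0.02) and paternally expressed imprinted genes (-0.07 and 0.12), which did not pass. Adjusted over the list alone 3 hypoxia and 3 stress genes were higher, 7 nervous system and 5 heart and muscle genes lower, and 4 matrix genes lower with 1 higher. The fibrillin Fbn1 (-2.42 ± 0.31, adjusted p = 0.195) and the muscle regulator Myod1 (-1.70 ± 0.25, adjusted p = 0.237) had the widest differences of the matrix and muscle lists. Without tamoxifen E11 replicate 2 the calls of Hox (0.083), proteases (0.166) and yolk sac (0.0705) ended, as they did without tamoxifen E13 replicate 1 (0.0825, 0.986 and 0.306), and that of matrix genes ended without tamoxifen E13 replicate 2 (0.172).

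Normal embryos of tamoxifen and control sires at E13 were compared across arrays, by channel. No gene differed past the threshold. The myelin protein Mobp read 1.05 ± 0.20 higher with tamoxifen sires, the alcohol dehydrogenase Adh1c 1.97 ± 0.68 higher and the adhesion protein Ceacam12 -1.22 ± 0.27, and the adjusted p of each was 1. Igf2 (0.10 ± 0.62), Afp (0.35 ± 0.79) and Mki67 (-0.02 ± 0.22) did not pass. Limma called 0 of 21096 genes, with 407 at an unadjusted p below 0.05, and 0 members of any list passed, also adjusted over each list alone. Without tamoxifen E13 replicate 1, Adh1c read 3.24 and Ceacam12 -1.75, but the tamoxifen side then rested on 1 sample in 1 dye.

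Among resorbed embryos at E13, the sire's treatment made no difference that passed for a single gene. The cortisol-inactivating enzyme Hsd11b2 read -1.30 ± 0.19 with tamoxifen sires (adjusted p = 0.293), the stress-induced cytokine Gdf15 -1.67 ± 0.38 (adjusted p = 0.356), and Mobp was at least 2.29-fold higher (1.20 ± 0.20, adjusted p = 0.311). Igf2 (1.16 ± 0.62, adjusted p = 0.75) and Cd68 (0.13 ± 0.38, adjusted p = 0.96) did not pass. The medians of the trophoblast and cell cycle lists were 0.42 and 0.33 higher with tamoxifen, with 0 members of either past the threshold, also adjusted over the list alone. Adjusted in that way, 1 complement and 1 hypoxia gene were higher, and 1 macrophage and 1 steroid list gene lower. Limma called 0 of 21096 genes, and 1446 had an unadjusted p below 0.05, against the 1055 that 5% would give. Without tamoxifen E13 replicate 1, Hsd11b2 read -1.50 and Mobp 1.02, but the tamoxifen side then rested on 1 sample in 1 dye.

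Normal embryos of tamoxifen sires were then compared between E13 and E11. Some genes of differentiating neurons and muscle and some placental genes were higher at E13, and list shifts were not tested between channels. The lens crystallin Cryba1 rose by 2.55 ± 0.12 (adjusted p = 6.42e-05), the microtubule protein Mapt by 1.88 ± 0.22 (adjusted p = 0.00757), the muscle regulators Myod1 and Myog by 1.73 ± 0.19 and 1.05 ± 0.13, and the placental cathepsins Ctsm and Ctsq by 2.41 ± 0.32 and 1.51 ± 0.20. The citrate transporter Slc13a5 fell by 2.91 ± 0.25 (adjusted p = 0.00436), Hamp by 2.38 ± 0.30, Il1rl1 by 2.83 ± 0.48 and the metalloproteinase inhibitor Timp3 by 1.82 ± 0.17. Of 26 nervous system genes 5 rose (18 adjusted over the list alone, median 0.71), with Tubb3 at 1.26 ± 0.21 and Dcx at 1.25 ± 0.21. Of 23 heart and muscle genes 5 rose (10 adjusted over the list alone, median 0.58), and of 28 trophoblast genes 3 rose, also adjusted over the list alone (median 0.36). In total 225 genes passed, 152 higher and 73 lower. Day and slide again cannot be told apart, and leaving out tamoxifen E11 replicate 2 left 1 gene, replicate 1 of that group 23, control E13 replicate 1 or 2 left 56, and tamoxifen E13 replicates 1 and 2 left 114 and 144. Of the 30 named genes that passed, 29 lost their call without tamoxifen E11 replicate 2, Cryba1 being the 1 that passed.

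Resorbed embryos of tamoxifen sires differed more between E13 and E11. Day and slide cannot be told apart here either, whichever array is left out. The prolactin-family genes Prl7a3 and Prl4a1 were higher at E13, with calls that depended on single arrays: Prl7a3 rose by 5.58 ± 1.15 (adjusted p = 0.0304) and Prl4a1 by 5.38 ± 1.10 (adjusted p = 0.0291), and the collagenase Mmp1 was at least 36.6-fold higher. The keratin Krt8 rose by 3.71 ± 0.77, Cxcl2 by 2.74 ± 0.52 and Hspa1a by 2.54 ± 0.39. Il1rl1 fell by 3.51 ± 0.48, Slc13a5 by 3.43 ± 0.25, Hamp by 3.42 ± 0.30 and Cd52 by 2.46 ± 0.22. Il1rl1, Slc13a5 and Hamp also fell in normal embryos. Of 23 hypoxia genes 5 rose (14 adjusted over the list alone, median 0.61), with Slc2a1 at 0.97 ± 0.11 and the glycolytic enzyme Pfkp at 1.05, and of 20 stress genes 4 rose (11 rose and 1 fell adjusted over the list alone, median 0.56), with haem oxygenase Hmox1 at 1.89 ± 0.27. Of 28 trophoblast genes 3 rose (4 adjusted over the list alone, median 1.24), and of 25 matrix genes 3 fell (5 adjusted over the list alone, median -0.20), Fbn1 by 2.41 ± 0.18. In total 973 genes passed, 307 higher and 666 lower. Leaving out tamoxifen E11 replicate 1 or 2 left 67 and 69 genes, tamoxifen E13 replicate 2 left 309 and replicate 1 of that group 2787, and control E13 replicate 1 or 2 left 564. Of 44 named genes that passed, 30 and 32 lost their call without tamoxifen E11 replicate 1 and 2. Prl7a3 lost its call without tamoxifen E11 replicate 1 (adjusted p = 0.194) or 2 (0.203) or tamoxifen E13 replicate 2 (0.147), and Mmp1 read 3.13 (adjusted p = 0.0904) without the last and also lost its call without control E13 replicate 1 or 2 (0.0603) or tamoxifen E11 replicate 1 (0.213) or 2 (0.206). Prl4a1, Krt8, Cxcl2, Hspa1a, Hmox1, Slc2a1 and Pfkp each lost their call without at least 1 tamoxifen array, with adjusted p of 0.241 for Krt8 (3.08), 0.199 for Cxcl2 (2.13), 0.201 for Prl4a1, 0.14 for Pfkp, 0.0881 for Hmox1, 0.0781 for Hspa1a and 0.0702 for Slc2a1 without tamoxifen E11 replicate 2. Il1rl1, Slc13a5, Hamp, Cd52 and Fbn1 passed whichever array was left out.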

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

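The tests of a dye effect, of compressed ratios and of a lower share of embryo tissue as the whole cause were chosen only after the results were seen. The other tests were not. No biological explanation was tested beyond the study's groups, and the sires, dams and litters of the embryos stay open.

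Between tamoxifen and control sires at E13, limma called 0 genes for the difference in the resorbed to normal ratio (556 at an unadjusted p below 0.05). Camera called 6 lists at its preset correlation. None of the 6 held with an estimated correlation (adjusted p = 0.82 each), and fry called 0 of 26 lists. The median difference was 0.35 for cell cycle, 0.50 for trophoblast, 0.09 for yolk sac and 0.10 for hypoxia genes, and -0.34 for macrophage and -0.65 for natural killer and T cell genes. Between E13 and E11 in the tamoxifen groups 7 genes passed, 5 of them with a current name: Penk (-3.27), Rflnb (-2.87), Cryba1 (-2.43), Kng2 (-2.12) and Add2 (-1.98). These calls did not hold: 0 genes passed without control E13 replicate 1 or 2, tamoxifen E11 replicate 1 or 2 or tamoxifen E13 replicate 2, nor with the replicate block, either filter setting, no background correction or the compared arrays alone. The lists that camera called at its preset correlation were hypoxia (0.52), stress (0.60), proteases (0.41), nervous system (-0.55), matrix (-0.42), heart and muscle (-0.32), yolk sac (-0.15) and Hox genes (-0.14). With an estimated correlation camera called 0 of these, and fry called 0 of 26. Stage cannot be told apart from slide in these. In the normal embryos themselves, the nervous system median was 0.71 and that of heart and muscle 0.58 higher at E13, whereas in resorbed embryos they were 0.08 and 0.16 higher.

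Trophoblast genes had different ratios on the control E13 arrays, with a median of -0.29 on replicate 1 and -2.52 on replicate 2. The normal channel gave a share of 0.0243 (interval -0.0916 to 0.115) of the difference in mean, which argues against different placental content of these normal samples. Intervals here are over list members and hold no spread between arrays. Over the other groups the replicate difference was -0.113 of that in control E13, against a dye effect. The resorbed channel held the rest, a share of 0.976 (interval 0.885 to 1.09), which is 1 minus the first share and shows only that the resorbed samples differed, with means of 10.51 on replicate 1 and 8.60 on replicate 2. Different placental content of the resorbed samples was not tested apart from this and stays open. The trophoblast list difference between tamoxifen and control rests in part on this array, since without control E13 replicate 2 it passed in the other direction (adjusted p = 0.038).

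Genes higher in resorbed embryos were raised less on tamoxifen E13 replicate 2 than on the other E13 arrays. The slope on control E13 replicate 2 was 0.545 over 2884 raised and 0.753 over 3895 lowered genes, a difference of -0.208 (interval over genes -0.235 to -0.183). Intervals over genes hold no spread between arrays. Between these arrays, ratios were thus not compressed alike for raised and lowered genes. Both slopes were under 1, so compression as part of it stays open. The normal channel gave a share of 0.276 (interval over genes 0.259 to 0.293) of the shortfall, between the bounds of 0.25 and 0.50 set in advance. Maternal tissue in the normal sample of that array is therefore left open as part of the shortfall. The resorbed channel gave the larger part: against control E13 replicate 2, the raised genes differed by -0.42 in the resorbed and 0.16 in the normal channel, and the lowered genes by 0.25 and -0.01. The macrophage and natural killer and T cell list differences between tamoxifen and control ended without this array (adjusted p = 0.953 and 0.782).

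Over all 3 groups, 23 of 27 yolk sac genes fell, and 13 of 17 decidua and 13 of 22 macrophage and leukocyte genes rose. Whether a lower share of embryo tissue was the whole cause stays open. The decidua median exceeded the macrophage median on 6 of 6 arrays, by 0.22 to 0.90 (exact sign-flip p = 0.0312, the smallest that 64 patterns can give). Over the 16 decidua and 18 macrophage genes well above background on every array, the medians were 1.38 and 1.00. Their difference was 0.38, with a bootstrap interval over members of -0.40 to 1.00. Neither result can decide the question. With a lower embryo share, the rise of a gene would depend on its level in the normal samples, so the medians need not be equal. Of 32 sign patterns of the 6 arrays, 1, the real one, gave as many called genes (13155, against at most 4633 in another). A share of 1 in 32 is the smallest this test can give, so it cannot exclude chance. The labels of tamoxifen E13 replicate 1 conflict, and its expression values went with the order used, so its sign is not independent of these data.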

How the results depend on the processing

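The deposited values on their mixed log scales were chosen as an alternative only after the data were seen. All other settings were planned. The cause of no difference between settings was tested, unless said otherwise above. The numbers of genes in resorbed against normal embryos moved with the scale, the channel order, the normalization and the arrays. With median centring they were 3700 in control E13, 1645 in tamoxifen E13, 1298 in tamoxifen E11 and 7701 over all 3 groups. With the deposited mixed scales they were 0 in control E13 and 0 in tamoxifen E11. With the channels of tamoxifen E13 replicate 1 exchanged, they were 0 in tamoxifen E13 and 0 over all 3 groups. The tamoxifen E13 arrays fitted alone gave 3027. Leaving out 1 array gave 4528 (without control E13 replicate 1) to 10466 (without tamoxifen E13 replicate 1) genes in control E13. In tamoxifen E13 it gave 3927 (without its replicate 1) to 7141 (without its replicate 2), in tamoxifen E11 852 (without its replicate 1) to 8222 (without tamoxifen E13 replicate 1), and over all 3 groups 10397 to 13376. The E13 minus E11 difference had 7 genes, but 1 with the scanner's log ratios and 1 with the deposited values on 1 scale. It had 0 with no background correction, median centring, scaling between arrays, no filter, the strict filter, the replicate number as a block (also the dye coefficient), the compared arrays alone, exchanged channels and the deposited mixed scales. Leaving out 1 array gave 0 to 100 genes for it (100 without tamoxifen E13 replicate 1). The tamoxifen minus control difference had 0 genes, and 0 to 114 when 1 array was left out. By channel, tamoxifen against control gave 0 to 60 genes in normal and 0 to 826 in resorbed embryos, the highest each without tamoxifen E13 replicate 1. E13 against E11 in normal embryos gave 141 with the replicate block, 61 with the strict filter, 0 with exchanged channels, and 1 (without tamoxifen E11 replicate 2) to 144 (without tamoxifen E13 replicate 2). In resorbed embryos it gave 212 with exchanged channels, and 67 (without tamoxifen E11 replicate 1) to 2787 (without tamoxifen E13 replicate 1). With an estimated correlation, on 3 residual degrees of freedom, camera called 0 lists in each of the 6 comparisons of ratios, and fry called 0 for both differences. When 1 array was left out, 3 to 8 lists differed between tamoxifen and control and 5 to 13 between E13 and E11. Directions reversed 3 times: Prf1 (-1.67) and Gzmb (-2.02), which had not passed, in tamoxifen E13 without its replicate 1 (2.97 and 3.30 without its replicate 2), and the trophoblast list between tamoxifen and control without control E13 replicate 2 (adjusted p = 0.038, against 6.94e-15 without control E13 replicate 1 and 0.215 without tamoxifen E13 replicate 2). Replicates of the same number showed no pairing shared by all groups, and 3 of 6 arrays correlated best with their own number. Deviations in control E13 correlated across genes at -0.116 with those in tamoxifen E13 and 0.0474 with those in tamoxifen E11. Between the tamoxifen groups they correlated at 0.34, where replicate number and dye orientation cannot be told apart. Each fit that left out an array rested on 1 array, in 1 dye orientation, for the group concerned, so its calls cannot be told apart from a dye effect. No block for slide was run, since slide and day coincide.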

Other observations

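The mast cell, lens crystallin and smooth muscle lists were chosen only after values were seen. Of 10 mast cell genes 9 rose and 1 fell in resorbed embryos over all 3 groups, also adjusted over the list alone (median 0.98). The mast cell proteases Mcpt1 and Mcpt8 rose by 2.32 ± 0.14 (SE, n = 6 arrays, adjusted p = 5.4e-05) and 2.29 ± 0.30 (adjusted p = 0.000821), and the interleukin-33 receptor Il1rl1 by 2.27 ± 0.18. The histamine-forming enzyme Hdc fell by 1.28 ± 0.15 (adjusted p = 0.00049). The list median was 1.38 in control E13, 0.99 in tamoxifen E13 and 0.71 in tamoxifen E11. The list was drawn up after several of its members were seen among the largest rises, so no test of it as a list is given.

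Of 10 lens crystallins 7 fell and 1 rose in resorbed embryos of control E13, also adjusted over the list alone (median -0.62). In tamoxifen E13 5 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.46), and in tamoxifen E11 0 fell and 1 rose (0 and 0 adjusted over the list alone, median 0.06). Between E13 and E11 the median differed by -0.37, with Cryba1 the 1 member that passed and 5 past adjusted over the list alone, all lower. This list too was drawn up after Cryba1 was seen, so no test of it as a list is given. Of 8 smooth muscle genes 5 fell and 1 rose over all 3 groups (median -0.31, camera adjusted p = 0.242, and adjusted p = 0.349 with an estimated correlation). The myosin light chain Myl9 fell by 2.39 ± 0.09 and the actin-binding protein Tagln by 1.25 ± 0.12, whereas the muscle filament desmin (Des) rose by 1.52 ± 0.14.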
